A study of Mus musculus with 5 samples.

How the data were processed

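The deposited values were UMI counts, 1 sparse matrix of genes by cell barcodes per library, made with Cell Ranger per the file headers. A UMI is the molecular tag that lets copies of the same transcript be counted once. The matrix headers named Cell Ranger 6.0.1 for rd1 libraries 1 and 2 and rd10 library 1, and Cell Ranger 7.0.1 for rd1 library 3 and rd10 library 2. Alignment to mm10 with Cell Ranger 7.0.1 and analysis with Seurat 4 were the steps given per the submitters' processing notes, so the headers and the notes differed for 3 libraries. Retinas were dissociated with papain and libraries were made with the 10x Genomics 3′ chemistry, per the labels' protocols. The protocol text of every sample, rd1 included, names 6 eyes of 3 rd10 mice, which conflicts with the design text, and the mouse numbers given here follow the design text. No cell annotation was used, and the matrices were filtered barcode lists whose lowest UMI total per barcode was 500 or 501.

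Barcodes with at least 500 genes and at most 20% mitochondrial UMIs were kept, which left 77992 of 84894. Scrublet scored doublets per library. Its own threshold marked between 10.7% and 30.3% of barcodes, so the highest scores were removed instead, up to the rate of 0.8% per 1000 cells that the loading implies, a choice made after the scores were seen. This removed 9974 barcodes and left 68018 cells. Cells were normalised to equal totals and log transformed, 2500 variable genes were taken, 40 principal components and 15 neighbours were used, and Leiden clustering ran at a resolution of 1. Genes of both phototransduction lists and mitochondrially encoded genes were left out of the variable genes. A joint clustering separated the libraries by Cell Ranger version, so cells were clustered within each version, a choice also made after the data were seen.

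Clusters were given cell class names from marker genes fixed before the data were examined, as were the gene lists, the tests and the rule for named genes. Each class name therefore stands for cells like that class by its markers. The score limits for a name (0.7, a broad score of 0.3, a mixed score of 0.65 and a doublet median of 0.15) were set after the scores were seen. The broad score served amacrine and cone bipolar cells, so a few of their clusters scored higher on another list. Of the 7.0.1 clusters, 15 (cone bipolar, 0.326) scored 0.417 on rod bipolar markers and 30 (amacrine, 0.422) scored 0.454 on horizontal markers. Cluster 10 of 6.0.1 (cone bipolar, 0.502) scored 0.664 on erythrocyte markers. The doublet limit took the name only where a cluster of the same class under the limit scored higher on its markers, so the clusters of astrocytes (doublet medians of 0.208 and 0.194), vascular cells (0.207 and 0.16) and 1 of microglia (0.169) kept their names above it. These limits, with the rules below, left 12 of 93 clusters unnamed. Those clusters held 2886 of 45625 rd1 cells (6.33%) and 1255 of 22393 rd10 cells (5.60%). A name was also lost where more markers of another class than of its own led a cluster. This took 26 of 6.0.1 (1660 cells) and 19, 36 and 42 of 7.0.1 (440, 346 and 111 cells). Cluster 34 of 7.0.1 (170 cells) had a low UMI count with no own marker among its leading genes. Clusters 26, 19 and 36 scored highest on bipolar lists, so shares of bipolar cells may be too low. Clec7a, a member of a microglial list, had no match in the files, and the horizontal cell marker Septin4 was matched under its older symbol Sept4. Vascular cells joined endothelial cells and pericytes. A class was tested if every library held at least 20 of its cells. Microglia were not tested because rd1 library 3 held 0 cells of that class.

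Counts were summed per library and class, and these sums were the replicates. Which mice went into which library is not given, so the libraries of a genotype may share mice. With all cells summed, the chi-square per degree of freedom between rd1 libraries 1 and 2 was 5.25. It was 299 to 477 for the other pairs within a genotype, which all cross Cell Ranger versions. Genes were kept with edgeR's filterByExpr, scaled with TMM and tested with the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05, rd10 relative to rd1, with no covariate (the planned fit). A fit with the Cell Ranger version as a block (the version-blocked fit) was added after the data were seen, since each version holds both genotypes. Only rd1 libraries 1 and 2 share both genotype and version. The spread between like libraries in that fit thus comes from this pair alone. Its adjusted p-values may look firmer than 3 against 2 libraries allow. CPM values are UMI counts scaled by library total and TMM factor, given as mean ± SD with n = 3 rd1 and n = 2 rd10 libraries. Log2 folds are from edgeR with their standard error (SE). Cones were compared with the summed non-photoreceptor cells of the same library with the library as a block. Cells of unnamed clusters were left out of both sums. Fixed lists were tested with camera at a preset correlation of 0.01 and, beside it, with an estimated correlation, adjusted with Benjamini-Hochberg over 111 tests. Class shares were compared with an exact two-sided permutation test over libraries. With 3 against 2 libraries its smallest p is 0.2, so no share can pass the threshold.

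Named genes were, for each class tested, the 8 largest rises and the 8 largest falls past the threshold with an average log2 CPM of at least 5 and no overlap between the rd1 and rd10 libraries, leaving out genes named Gm with a digit, Rik genes and sex-linked genes. For each list described, up to 4 members past the threshold with the largest absolute fold were named. All members of the cone phototransduction list in cones, Pde6b and Kcnj6 were named in any case. The rule was applied to both fits, the second time as a choice made after the data were seen. Genes named outside the rule are said to be, and a few results the rule would name are not reported here.

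Alternatives were DESeq2, DESeq2 size factors in edgeR, no filter and a stricter filter on low counts, the sample number as a block, each library left out in turn, doublets kept, a stricter cell filter, a finer clustering, thinned counts, another denominator and an edgeR test for shares, and cone bipolar cells alone as the comparison for cones. The version block, the 6.0.1 libraries alone, each version or genotype alone, cones without a rod transcript and the tests of 4 further classes were added after the data were seen. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs and again from all UMIs. Intervals of shares are 95% Wilson intervals and floors are 3 counts of the total; both cover counting error only.

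On simulated counts with 100 genes changed by a log2 fold of 2, the planned fit recovered 41% in cones, 61% in Müller glia, 39% in rod bipolar cells, 14% in cone bipolar cells and 23% in amacrine cells. At a log2 fold of 1 it recovered 1%, 4%, 2%, 0% and 0% in the same order. The version-blocked fit recovered 73% to 100% of genes at a log2 fold of 1 and 98% to 100% at 2, with between 5 and 14 false calls per class. The changed genes had an average log2 CPM of at least 5. Counts were drawn independently from each fit's own means and dispersion trend. Mice shared between libraries and spread particular to a gene are thus not covered. Gene positions were taken from a GRCm38 annotation, in which 32235 of 32285 gene identifiers (99.8%) were found, and are 1-based. The software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.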

Results

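Single-cell RNA was measured in dissociated retinas of mice with 2 forms of inherited photoreceptor degeneration. The rd1 and rd10 strains both carry a mutation in Pde6b, which encodes a subunit of the rod cGMP phosphodiesterase, and rods die early in both, followed by slow loss of cone function. Cells of 5 rd1 mice, aged PND112 to PND116, were pooled into 3 libraries, and cells of 6 rd10 mice at PND126 were pooled into 2. Age, and any difference in sex or strain background, therefore went with genotype. No wild-type retina was measured, so all values describe retinas after rod loss.

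The 5 libraries held 20660, 20422 and 16257 barcodes for rd1 libraries 1, 2 and 3, and 16644 and 10911 for rd10 libraries 1 and 2. Their totals were 52400744, 31991956 and 125000056 UMIs for rd1 and 46242144 and 119370032 UMIs for rd10. The median per barcode was 1798, 1268 and 6001 UMIs in rd1 and 2100 and 8603 UMIs in rd10. The deeper library of each genotype was processed with Cell Ranger 7.0.1 and the others with 6.0.1. After filters, 15590, 15985 and 14050 rd1 cells and 12672 and 9721 rd10 cells remained.

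The first question was which cell types were present and in what shares. Cones, the cells that a therapy acting on the phototransduction cascade would need, made up 1.28% ± 0.233 (SD, n = 3) of rd1 cells and 4.80% ± 0.186 (SD, n = 2) of rd10 cells, a ratio of 3.75. The ratio was 3.98 among the 6.0.1 libraries and 3.30 among the 7.0.1 libraries. Rods were found as a class in rd10 library 2 alone, with 142 cells, or 1.46% (95% Wilson interval 1.24 to 1.72). Inner retinal classes made up most cells: amacrine cells 27.0% ± 8.60 in rd1 and 28.0% ± 2.59 in rd10, cone bipolar cells 27.1% ± 1.72 and 27.3% ± 1.5, and rod bipolar cells 10.3% ± 1.11 and 12.4% ± 2.11. Müller glia, the main glia of the retina, made up 21.3% ± 7.34 and 15.03% ± 2.41.

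Cones were counted as 204 cells (1.31%, 95% Wilson interval 1.14 to 1.5), 165 (1.03%, 0.887 to 1.20) and 210 (1.49%, 1.31 to 1.71) in rd1 libraries 1, 2 and 3. In rd10 libraries 1 and 2 they were 591 (4.66%, 4.31 to 5.04) and 479 (4.93%, 4.51 to 5.38). The groups did not overlap, and the exact two-sided permutation test gave p = 0.2, the smallest it can give, with a Benjamini-Hochberg adjusted p of 0.8 over 12 classes. On cell counts, edgeR gave a log2 fold of 1.91 for cones with a Benjamini-Hochberg adjusted p of 0.00479, the 1 class past the threshold. With the Cell Ranger version as a block it was 1.88 with an edgeR Benjamini-Hochberg adjusted p of 0.00153. Ganglion cells, the output neurons, made up 4.17% ± 0.877 in rd1 and 2.86% ± 0.174 in rd10, again without overlap, with an edgeR log2 fold of -0.54 that did not pass (Benjamini-Hochberg adjusted p = 0.377). Horizontal cells made up 1.17% ± 0.491 and 1.19% ± 0.240, vascular cells 0.437% ± 0.0508 and 0.657% ± 0.104, and astrocytes 0.341% ± 0.117 and 0.262% ± 0.0804. In the other 4 libraries 0 cells were named as rods, but a few rods need not form a cluster of their own, and cluster 20 of the 6.0.1 libraries, named as cones, scored 0.932 on the rod markers, so no limit on their share follows. Dissociation and droplet loading can set such shares, and unnamed clusters held 6.33% of rd1 and 5.60% of rd10 cells. The largest of these, cluster 26 of 6.0.1 with 1660 cells, scored highest on cone bipolar markers (0.547), so the share of cone bipolar cells may be too low.

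**Figure D1:**
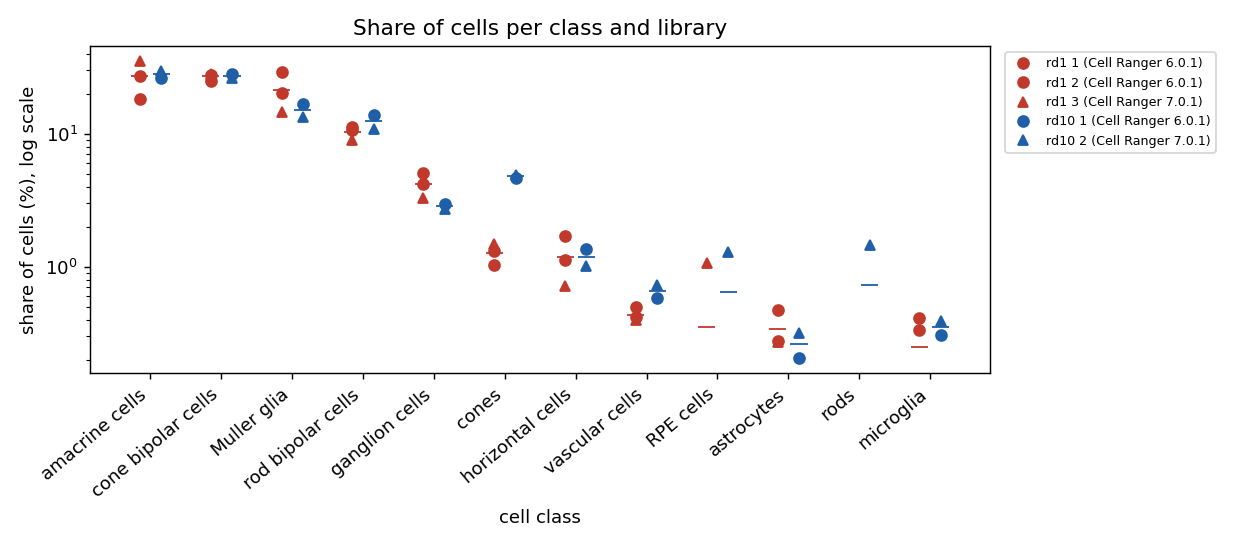
Share of cells in each class (y axis, %, log scale) per library, with the Cell Ranger version as the marker shape and horizontal lines for the mean of each genotype; shares of 0 are not drawn. Cones lie between 1.03% and 1.49% in rd1 and between 4.66% and 4.93% in rd10.

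The next question was which parts of the light-signalling cascade the remaining cones held. Summed over cells, cones carried transcripts of almost the whole cascade: 20 of 21 cone phototransduction genes were higher in cones than in the non-photoreceptor cells of the same library, with a median log2 fold of 5.70. Opn1sw, the short-wavelength opsin, lay at 6125 ± 1459 CPM (SD, n = 5) in cones against 20.4 ± 9.74 CPM in the other cells, and Opn1mw, the medium-wavelength opsin, at 3185 ± 880 CPM (SD, n = 5). Gnat2, the cone transducin, lay at 1757 ± 307 CPM and Pde6c, the catalytic subunit of the cone phosphodiesterase, at 1767 ± 1182 CPM. Kcnj6, which encodes the GIRK2 potassium channel subunit opened by G proteins, was lower in cones, at 3.80 ± 3.15 CPM against 57.7 ± 48.9 CPM in the other cells.

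By edgeR with Benjamini-Hochberg adjustment over 15198 genes, Opn1sw was higher by a log2 fold of 8.34 (SE 0.351, adjusted p = 1.21e-09), in 5 of 5 libraries. Arr3, the cone arrestin that shuts off opsin, was higher by 8.12, Opn1mw by 7.99, Pde6h, the inhibitory phosphodiesterase subunit, by 7.86, and Guca1a, a calcium sensor of guanylate cyclase, by 7.74. Cnga3 and Cngb3, the subunits of the cone cyclic nucleotide-gated channel, were higher by 7.71 and 4.70, Grk1, the opsin kinase, by 7.37, and Pdc, which binds transducin beta and gamma subunits, by 7.29. Left out of the other cells were unnamed clusters 26 of 6.0.1 and 19 and 36 of 7.0.1, with Cngb3 among their leading genes. They scored highest on bipolar lists and lost their name to markers of another class, so the fold of Cngb3 may be too high. Gnat2 was higher by 5.70, Guca1b by 5.43, Gngt2 by 4.98, Rgs9 by 4.40, Gucy2e by 3.32, Rgs9bp by 3.15 and Gnb3 by 2.88. Slc24a2, the cone sodium-calcium exchanger, was higher by 1.69 and Gnb5 by 1.02. Gucy2f did not pass, at 1.12 CPM in cones and 4.47 CPM in the other cells (edgeR log2 fold -1.80, Benjamini-Hochberg adjusted p = 0.0729). Of the 21 genes, 10 also served as markers to name cones, which makes their height in cones partly circular. Of the 11 others, 10 were higher in cones, with a median log2 fold of 4.40.

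All 4 GIRK subunit genes were lower in cones, Kcnj6 by a log2 fold of -3.99 (SE 0.299, edgeR Benjamini-Hochberg adjusted p = 1.81e-07), Kcnj5 by -2.59, Kcnj9 by -2.45 and Kcnj3 by -2.16. Against cone bipolar cells alone Kcnj3 was not lower, with a log2 fold of 0.43. Pde6b, the mutated gene, was low but higher in cones, at 7.85 ± 7.78 CPM (SD, n = 5; edgeR log2 fold 2.20, SE 0.609, Benjamini-Hochberg adjusted p = 0.00778), in 4 of 5 libraries. Its cone UMIs numbered 1, 0 and 11 in rd1 libraries 1, 2 and 3, so rd1 library 3 held most of them. In rd10, 2.23% of cones and 2.35% of Müller glia had a UMI from all UMIs, and 0.884% and 0.292% after thinning. Whether Pde6b lay above background in rd10 cones thus stays open. The difference between cones and other cells changed with genotype by -3.50 log2 units (edgeR interaction test, Benjamini-Hochberg adjusted p = 0.0326). In the 142 rods of rd10 library 2 Pde6b had 353 UMIs, with a UMI in 77.5% of cells against 2.63% of Müller glia in that library. Kcnj6 had 18 UMIs there, with a UMI in 4.93% of cells against 3.09% of Müller glia, so its expression in rods stays open. All 21 outer segment and cilium genes were higher in cones, with a median log2 fold of 4.50, among them Rp1l1 (7.91), Impg1 (7.84), Rp1 (7.46) and Aipl1 (6.91). Photoreceptor transcription factors were higher for 12 of 13, among them Samd7 (7.28), Prdm1 (6.84) and Crx (3.58), the regulator of photoreceptor genes, while Rorb was lower (-1.16). Of these 13, 3, Crx included, also served as markers to name cones, and 9 of the 10 others were higher. Photoreceptor synapse genes were higher for 13 of 16, among them Cabp4 (6.90), Elfn1 (3.75) and Cplx4 (3.64). Rod phototransduction genes were higher in cones for 9 of 11, led by Sag (6.98), Pde6g (6.90), Pde6a (4.62) and Gngt1 (4.60). Gngt1 was among the genes leading unnamed clusters 26 of 6.0.1 and 36 of 7.0.1, which the comparison left out, so its fold may be too high.

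**Figure D2:**
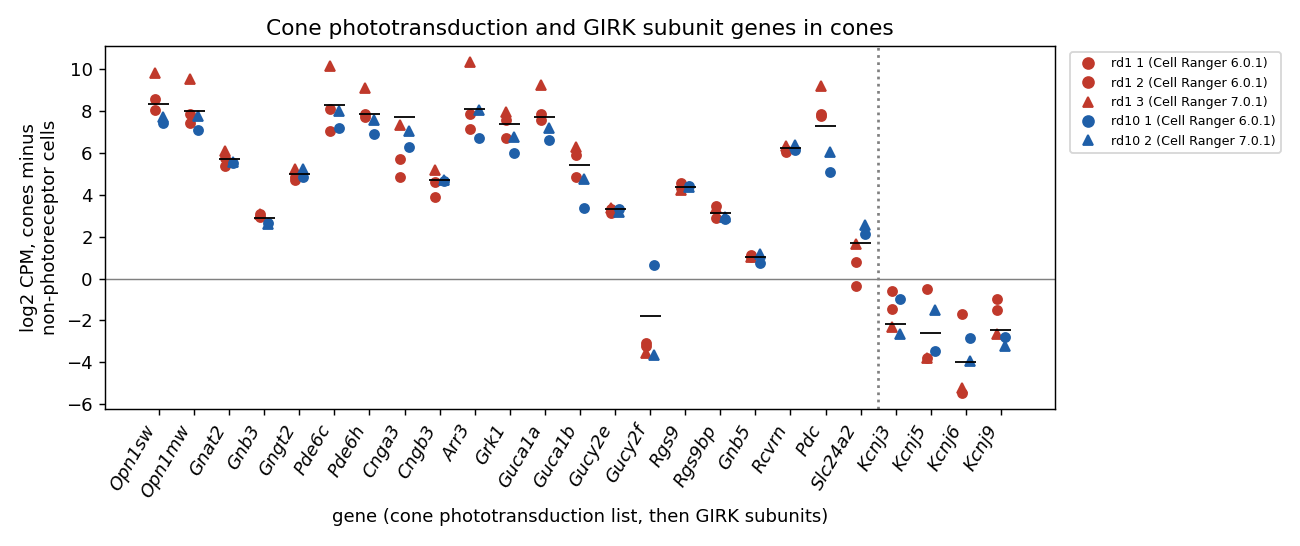
Log2 CPM in cones minus that in non-photoreceptor cells (y axis) per library for each cone phototransduction gene and the 4 GIRK subunits, with black lines for the edgeR log2 fold. Opn1sw lies highest at 8.34, Gucy2f lies at -1.80 and Kcnj6 at -3.99.

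The share of cones with at least 1 UMI followed after thinning each cell to 1000 UMIs, which left out 135 of the rd1 cones and 76 of the rd10 cones as too shallow. Opn1sw was seen in 74.5% ± 5.85 (SD, n = 3) of rd1 cones and 54.8% ± 11.9 (SD, n = 2) of rd10 cones, against a background in Müller glia, which should lack it, of 1.62% and 2.38%. From all UMIs the shares were 77.5% ± 3.89 and 61.5% ± 3.72, against 4.22% and 12.9%. Gnat2 was seen in 82.5% ± 5.56 and 70.6% ± 10.3 of thinned cones, against 0.806% and 1.47% of Müller glia, and in 84.5% ± 7.59 and 87.3% ± 3.53 from all UMIs, against 2.59% and 8.51%, so the order of the genotypes turned with depth. Pde6c was seen in 56.3% ± 24.1 and 85.9% ± 10.0, against 0.130% and 1.23% of Müller glia, and in 70.9% and 95.02% from all UMIs. Some other members were seen in few thinned cones. Cnga3 was seen in 5.22% of rd1 and 11.4% of rd10 cones and Guca1b in 4.58% and 4.22%. Gucy2e was seen in 12.3% and 12.9% and Rgs9bp in 14.0% and 14.6%. From all UMIs Cnga3 was seen in 12.9% of rd1 and 32.5% of rd10 cones. Kcnj6 was seen in 0.202% ± 0.350 of rd1 and 0.202% ± 0.0132 of rd10 cones, with 0.212% and 0.140% in Müller glia, and in 0.808% and 1.51% from all UMIs, with 1.07% and 1.76% in Müller glia, so Kcnj6 in cones lay at background. Median depths in cones were 1871, 959 and 4010 UMIs in rd1 libraries 1, 2 and 3 and 2271 and 6118 in rd10 libraries 1 and 2. In Müller glia they were 3367, 1550, 8574, 4482 and 13392 in the same order, and thinning left out 489 rd1 and 28 rd10 Müller glia.

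Between the genotypes, the composition of the cone cascade differed by gene when the Cell Ranger version was a block. In rd10 cones Slc24a2 was higher, at 818 ± 675 CPM (SD, n = 2) against 175 ± 186 CPM (SD, n = 3), and so were the phosphodiesterase genes Pde6c, at 2652 ± 1156 against 1149 ± 869 CPM, and Pde6h, at 8739 ± 2248 against 4709 ± 1009 CPM. The channel gene Cnga3 was higher too, at 126 ± 36.4 against 55.8 ± 32.7 CPM. Pdc was lower, at 536 ± 152 against 1153 ± 257 CPM, and so was Opn1sw, at 4642 ± 1219 against 7121 ± 446 CPM. These 6 of 20 measured genes passed in the version-blocked fit and 0 passed in the planned fit.

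In the version-blocked edgeR fit with Benjamini-Hochberg adjustment, Slc24a2 rose by a log2 fold of 1.92 (SE 0.192, adjusted p = 2.56e-09; 2.42 in the 6.0.1 and 1.74 in the 7.0.1 libraries). Pde6c rose by 1.12 (SE 0.175, adjusted p = 2.03e-05; 1.52 and 0.70), Pde6h by 0.98 (adjusted p = 2.76e-05; 0.97 and 1.00) and Cnga3 by 0.95 (adjusted p = 0.00326; 1.43 and 0.70), all by edgeR with Benjamini-Hochberg adjustment. Pdc fell, with a log2 fold of -1.12 (SE 0.187, edgeR Benjamini-Hochberg adjusted p = 4.98e-05; -0.65 and -1.72), and Opn1sw fell, with -0.59 (SE 0.163, edgeR Benjamini-Hochberg adjusted p = 0.0223; -0.42 and -0.81). The 14 others did not pass, among them Opn1mw (0.23), Gnat2 (-0.24), Arr3 (-0.080) and Cngb3 (0.38). Adjusted over the list alone, the same number of 6 passed. Camera on the list gave a Benjamini-Hochberg adjusted p of 0.206, and an adjusted p = 0.835 with an estimated correlation. In the planned edgeR fit 0 of 20 passed, also when adjusted over the list alone, with 2 at an unadjusted p under 0.05 and 0 by DESeq2. In the version-blocked edgeR fit Opn1sw did not pass without rd1 library 1, without rd1 library 2 or with doublets kept (Benjamini-Hochberg adjusted p = 0.0577, 0.137 and 0.0633), and Cnga3 did not pass with version-blocked DESeq2 (Benjamini-Hochberg adjusted p = 0.195).

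**Figure D3:**
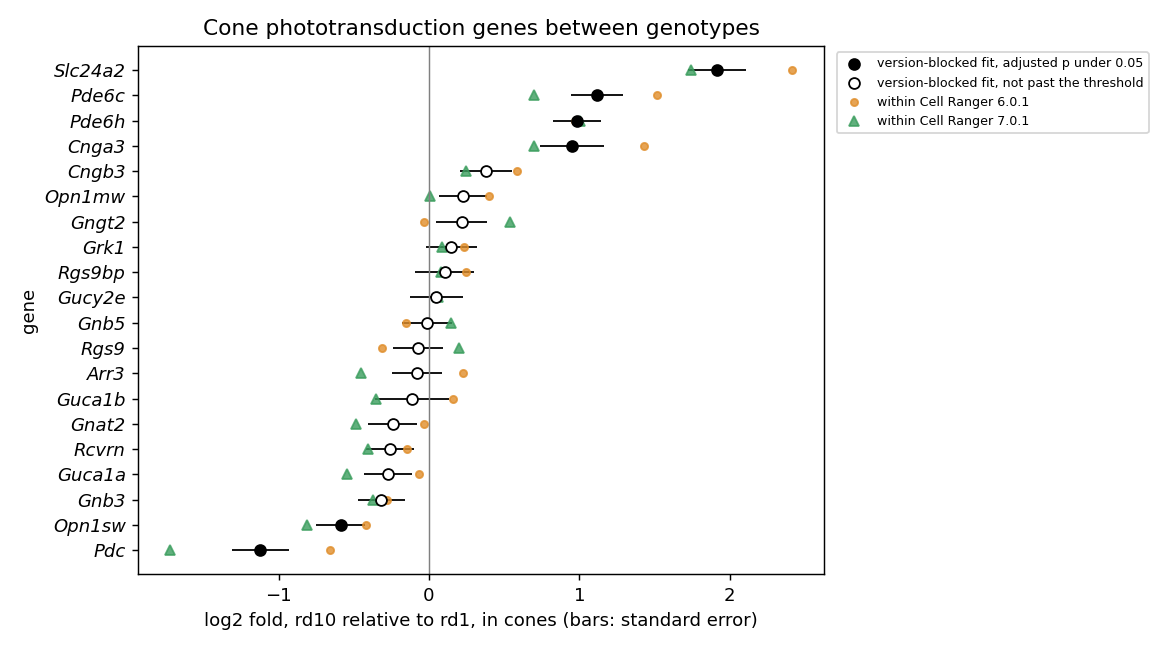
Log2 fold of rd10 relative to rd1 in cones (x axis) for each cone phototransduction gene in the version-blocked fit, with standard errors, and within each Cell Ranger version. Filled points are the 6 genes with an adjusted p under 0.05, from Slc24a2 at 1.92 to Pdc at -1.12.

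Other genes measured in cones moved further than the cascade. Igfbp2, a binding protein of insulin-like growth factors, lay at 125 ± 21.6 CPM in rd1 and 5.15 ± 2.42 CPM in rd10 cones, and Frmpd1, a scaffold protein gene, at 107 ± 17.5 and 5.72 ± 0.531 CPM. Arhgdib, a regulator of small GTPases, lay at 2.98 CPM in rd1 and 84.2 ± 12.6 CPM in rd10.

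In all, 543 genes passed in cones in the version-blocked fit, 322 higher and 221 lower, and 155 by DESeq2. In this fit only rd1 libraries 1 and 2 share both genotype and version, so its small p-values rest on few like libraries. The planned edgeR fit called 1 gene of 9502, Xist, with 406 at an unadjusted p under 0.05 and 56 by DESeq2. It called 0 genes without rd1 library 1 or rd1 library 2 and 12 without rd1 library 3. Arhgdib rose by a log2 fold of 4.83 (SE 0.428, version-blocked edgeR, Benjamini-Hochberg adjusted p = 1.65e-10). The other largest rises were Fbxw21 (3.71), Elk3 (3.31), Ptprn2 (3.26), Rpl29 (2.97), Tmbim1 (2.52), Dlgap1 (2.38) and AC149090.1 (2.38). Igfbp2 fell, with a log2 fold of -4.63 (SE 0.303, version-blocked edgeR, Benjamini-Hochberg adjusted p = 8.58e-14), beside Tmem132c (-5.84), Rtkn2 (-5.50), Frmpd1 (-4.30), Amotl1 (-3.31), Me3 (-3.16), Dnaic1 (-3.14) and AA465934 (-2.89). In the planned edgeR fit the Benjamini-Hochberg adjusted p was 0.0600 for Igfbp2 and 0.0514 for Frmpd1. Igfbp2 and Tmem132c were also among the genes leading clusters of amacrine cells, and Dnaic1 of cone bipolar cells. RNA from those cells was not tested as a source of their values in cones.

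Of the 13 mitochondrially encoded genes, 11 rose in the version-blocked fit, led by mt-Nd3 (1.95), mt-Atp8 (1.61), mt-Nd4l (1.45) and mt-Nd2 (0.98), and all 13 passed when adjusted over the list alone. Camera gave a Benjamini-Hochberg adjusted p of 6.55e-21, lost with an estimated correlation (adjusted p = 0.492 with an estimated correlation). In the planned edgeR fit 0 of 13 passed and 6 did when adjusted over the list alone. Over all barcodes the median mitochondrial share of UMIs was 2.57%, 2.46% and 2.31% in rd1 libraries 1, 2 and 3 and 3.86% and 2.32% in rd10 libraries 1 and 2, so rd10 library 1 stood apart. Heat shock genes rose for 2 of 11, Hspa1b (1.51) and Hspa5 (0.76), with a camera Benjamini-Hochberg adjusted p of 0.00895 and an adjusted p = 0.679 with an estimated correlation. Of the ON bipolar list, 2 of 11 fell, Pcp2 (-0.81) and Trpm1 (-0.75), with a camera Benjamini-Hochberg adjusted p of 0.0309 and an adjusted p = 0.693 with an estimated correlation. Of rod genes in cones, Pde6a fell, with a log2 fold of -1.5 (version-blocked edgeR, Benjamini-Hochberg adjusted p = 3.20e-07), from 213 ± 6.42 to 75.6 ± 21.5 CPM. Pde6b lay at 5.20 ± 6.98 CPM in rd1 and 11.2 ± 8.89 CPM in rd10 cones and did not pass (version-blocked edgeR log2 fold 0.26, Benjamini-Hochberg adjusted p = 0.914).

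Müller glia, which support neurons and react to injury, held the most genes past the threshold in the planned fit. Anxa1, an anti-inflammatory annexin, rose from 12.04 ± 4.02 CPM (SD, n = 3) in rd1 to 275 ± 58.8 CPM (SD, n = 2) in rd10, and A2m, the protease inhibitor alpha-2-macroglobulin, from 7.83 ± 1.35 to 75.4 ± 2.56 CPM. Nbl1, a secreted BMP antagonist, rose from 16.6 ± 3.26 to 188 ± 15.5 CPM. Lgals3, the lectin galectin-3, fell from 116 ± 15.7 to 18.6 ± 2.72 CPM, and Hopx, a homeodomain protein, from 304 ± 18.9 to 97.8 ± 10.4 CPM. In the version-blocked fit 13 of 21 interferon response genes rose, with an adjusted p = 0.581 with an estimated correlation for the list, and the planned edgeR fit called 0 of 21, or 11 when adjusted over the list alone. Gfap, the intermediate filament of reactive glia, fell in the version-blocked fit.

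The planned edgeR fit called 63 genes of 15131 in Müller glia, 41 higher and 22 lower, and DESeq2 called 529. The version-blocked fit called 1961, 1108 higher and 853 lower. Anxa1 rose by a log2 fold of 4.51 (SE 0.340, planned edgeR fit, Benjamini-Hochberg adjusted p = 0.0238; 4.52 in the 6.0.1 and 4.21 in the 7.0.1 libraries), Nbl1 by 3.50 (SE 0.225, adjusted p = 0.0215) and A2m by 3.27 (SE 0.204, adjusted p = 0.0215). The other largest rises were Trf, the transferrin gene, by 2.83, Kcnk1, a potassium channel, by 2.79, Rpl29 by 2.56, and the calcium-binding S100a11 and S100a10 by 2.51 and 2.44. Lgals3 fell, with a log2 fold of -2.64 (SE 0.215, planned edgeR fit, Benjamini-Hochberg adjusted p = 0.0272). AA465934 (-4.49), Rnf121 (-2.30), Qpct (-2.27), BC004004 (-2.16), Hddc3 (-2.02), Alad (-1.72) and Hopx (-1.64) fell as well. In the version-blocked fit Prss56, a protease gene, fell by 6.35, from 76.4 to 0.823 CPM, Syt1 by 2.17 and Pigz by 2.04. Without rd1 library 1 the planned edgeR fit called 0 genes, without rd1 library 2 also 0, without rd1 library 3 it called 28, and without rd10 library 1 or 2 it called 1 in each case.

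**Figure D4:**
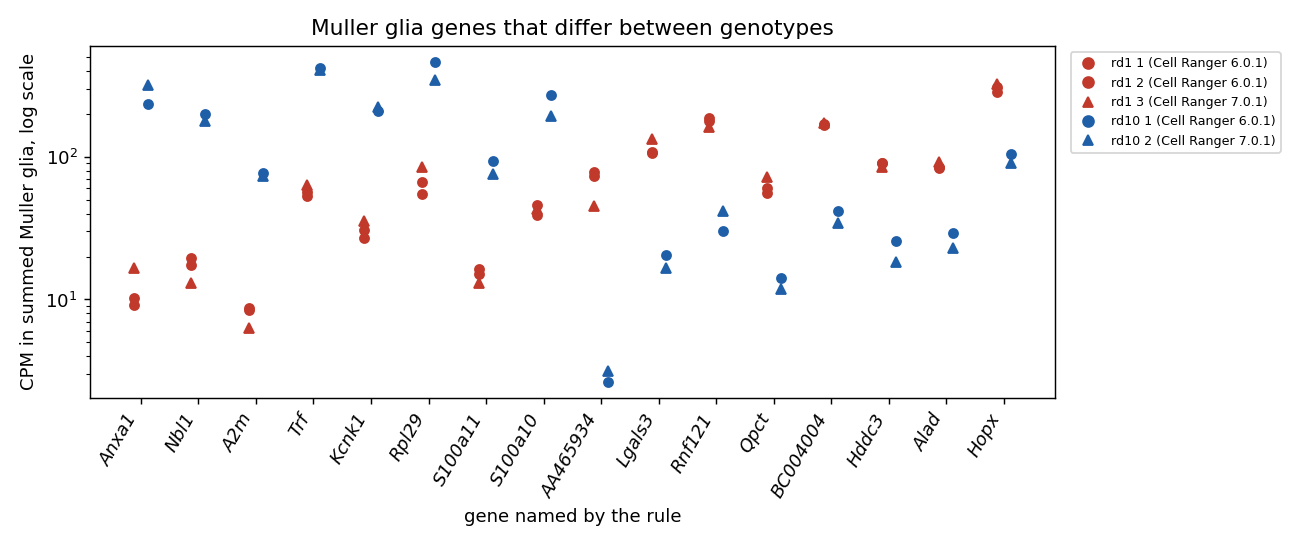
CPM in summed Müller glia (y axis, log scale) per library for the genes that the naming rule gave in the planned fit, with marker shape for the Cell Ranger version. Anxa1 lies at a mean of 12.04 CPM in rd1 and 275 CPM in rd10, and Lgals3 at 116 and 18.6 CPM.

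Of the interferon response list, 13 of 21 rose in Müller glia in the version-blocked fit and 20 when adjusted over the list alone, led by Ifit1 (2.59, from 6.39 ± 3.02 to 32.9 ± 2.20 CPM), Rsad2 (2.45), Rtp4 (2.27) and Usp18 (1.85). Camera gave a Benjamini-Hochberg adjusted p of 6.41e-18 and an adjusted p = 0.581 with an estimated correlation. Reactive gliosis genes rose for 6 of 17 and fell for 1, with A2m (3.33), Lcn2 (1.85), an acute-phase lipocalin, Serpina3n (1.44) and Socs3 (1.28) higher; 8 passed when adjusted over the list alone. The camera Benjamini-Hochberg adjusted p was 0.000851, with an adjusted p = 0.492 with an estimated correlation. Gfap fell, with a log2 fold of -1.17 (version-blocked edgeR, Benjamini-Hochberg adjusted p = 0.000251), from 180 ± 47.3 to 73.5 ± 10.1 CPM. Complement genes rose for 3 of 9, C4b (1.82), Serping1 (1.56) and C1ra (1.43), and fell for Cd59a (-1.37), with a camera Benjamini-Hochberg adjusted p of 0.0289 and an adjusted p = 0.681 with an estimated correlation. Immediate early genes rose for 3 of 16, Klf2 (3.77), Atf3 (1.19) and Zfp36 (0.99), with a camera Benjamini-Hochberg adjusted p of 0.00397 and an adjusted p = 0.835 with an estimated correlation. Glycolysis genes fell for 8 of 24 and rose for 3, with Eno2 (-1.04) and Pfkl (-0.66) lower and Txnip (0.97) and Slc2a1 (0.68) higher, at a camera Benjamini-Hochberg adjusted p of 0.0458 and an adjusted p = 0.835 with an estimated correlation. Of 12 genes of normal Müller function 1 rose, Car2 (0.48), and 2 fell, Dio2 (-0.99) and Kcnj10 (-0.54), in the version-blocked fit, and the list did not pass (camera Benjamini-Hochberg adjusted p = 0.825, adjusted p = 0.973 with an estimated correlation). Glul lay at 8173 and 8717 CPM and Rlbp1 at 2752 and 3223 CPM.

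The clusters behind Müller glia differed between libraries, and the depth of the clusters differed too. Among the 6.0.1 libraries cluster 5 held 65.8% of rd1 and cluster 3 held 76.3% of rd10 Müller glia, and among the 7.0.1 libraries cluster 4 held 99.5% of rd1 and cluster 49 held 98.8% of rd10 Müller glia. Among the genes leading cluster 3 were Ccn1, Zfp36, Cebpd, Ier2, Socs3, Fosb and Atf3, and it held 1446 and 1228 cells of rd1 libraries 1 and 2 and 1618 of rd10 library 1. Among those leading cluster 4 were Atf5, Nupr1, Zfp36l1, Ier2 and Junb, and among those leading cluster 49 were Anxa1, Trf and Mt2. Clusters 5 and 3 had medians of 1754 and 3567 UMIs. Müller glia of rd1 libraries 1 and 2 and rd10 library 1 had medians of 3367, 1550 and 4482 UMIs. Clusters 4 and 49 had medians of 8574 and 13443 UMIs, and each genotype had 1 library of 7.0.1. Depth and library therefore cannot be told apart from genotype in these clusters.

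Photoreceptor transcripts were also higher in rd10 Müller glia, as a low level in cells that should lack them. Rod phototransduction genes rose for 10 of 11 in the version-blocked fit, among them Pde6b (5.44), Cnga1 (5.16) and Cngb1 (4.24). Cone phototransduction genes rose for 11 of 20, among them Pde6c (2.99), Guca1b (2.80), Pde6h (2.31) and Pdc (2.00), and outer segment genes for 12 of 20, among them Rp1 (3.59). The camera Benjamini-Hochberg adjusted p was 7.88e-27, 9.04e-12 and 1.24e-10 for these lists, with adjusted p = 0.492, 0.581 and 0.492 with an estimated correlation. Photoreceptor transcription factors rose for 4 of 12, among them the rod factors Nr2e3 (5.25) and Nrl (3.74) and the cone factor Rxrg (1.70), and Prdm1 fell (-1.32), with a camera Benjamini-Hochberg adjusted p of 0.0302 and an adjusted p = 0.581 with an estimated correlation. Mitochondrially encoded genes rose for 6 of 13, led by mt-Nd3 (1.69), with a camera Benjamini-Hochberg adjusted p of 2.23e-06 and an adjusted p = 0.492 with an estimated correlation.

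Rod bipolar cells, which lose their rod input in both strains, differed in few genes in the planned fit, but by much. Cngb1, known as the rod cyclic nucleotide-gated channel subunit, rose from 8.04 ± 1.52 CPM (SD, n = 3) to 140 ± 10.1 CPM (SD, n = 2). Cfi, complement factor I, rose from 0.377 to 65.3 CPM, and the long non-coding RNA Sox2ot from 27.1 to 185 ± 3.20 CPM. In the version-blocked fit Stmn1, a microtubule regulator, fell from 462 to 101 CPM, Syn2, a synaptic vesicle protein gene, from 77.4 to 7.82 CPM, and Wnt5a, a secreted signal, fell as well.

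The planned edgeR fit called 5 genes of 12428, with 735 at an unadjusted p under 0.05 and 184 by DESeq2. They were Cngb1 (log2 fold 4.10, SE 0.214, adjusted p = 0.0289), Sox2ot (2.77, SE 0.178, adjusted p = 0.0452), Cfi (7.12, adjusted p = 0.0452), 6430590A07Rik (3.73, adjusted p = 0.0452) and Xist (-14.03, adjusted p = 0.0289), all by edgeR with Benjamini-Hochberg adjustment. Cfi, 6430590A07Rik and Xist fall outside the naming rule and were picked after their values were seen. Leaving out rd1 library 1, rd1 library 2 or rd10 library 1 left 0 genes in the planned edgeR fit, leaving out rd10 library 2 left 1 and leaving out rd1 library 3 left 2. The version-blocked fit called 814 genes, 484 higher and 330 lower, and 504 without rd1 library 1. Slc5a8, a monocarboxylate transporter gene, had 0 UMIs in all 3 rd1 libraries and was at least 341-fold higher in rd10, at 113 unscaled CPM against a floor of 0.332 CPM over the rd1 libraries. Pttg1 (8.27), Cngb1 (4.09), Shisa4 (3.49), Galnt14 (2.85), Sox2ot (2.79), Rpl29 (2.67) and Sema3e (2.60) were the other largest rises. Mfng (-4.06), AA465934 (-3.93), Syn2 (-3.35), Rnf121 (-2.95), the cadherin gene Cdh11 (-2.52), Wnt5a (-2.39), Mpped2 (-2.27) and Stmn1 (-2.16) were the largest falls.

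Rod phototransduction genes rose for 9 of 10 in rod bipolar cells in the version-blocked fit, among them Cnga1 (7.89), Cngb1 (4.09) and Gnat1 (2.69), with a camera Benjamini-Hochberg adjusted p of 7.88e-27 and an adjusted p = 0.492 with an estimated correlation. Cone phototransduction genes rose for 6 of 17 and fell for 2, among them Pdc (2.25), Pde6c (1.95), Cngb3 (-1.90) and Pde6h (1.53), with a camera Benjamini-Hochberg adjusted p of 0.000851 and an adjusted p = 0.681 with an estimated correlation. Of 3 complement genes, Cfi rose (7.11) and Cd59a fell (-1.57), with a camera Benjamini-Hochberg adjusted p of 0.00165 and an adjusted p = 0.492 with an estimated correlation. Mitochondrially encoded genes rose for 3 of 13, with a camera Benjamini-Hochberg adjusted p of 1.01e-06 and an adjusted p = 0.581 with an estimated correlation. Among the 6.0.1 libraries cluster 21 held 81.4% of rd1 and cluster 27 held 95.4% of rd10 rod bipolar cells, and among the 7.0.1 libraries cluster 0 held 89.4% and cluster 1 held 76.0%. Median UMIs were 1010.5 and 1885 in clusters 21 and 27 and 3605.5 and 6643 in clusters 0 and 1. Cluster 27 held 616 cells of rd1 library 1 and 23 of rd1 library 2. Depth and genotype therefore cannot be told apart in these clusters.

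Cone bipolar cells, which carry cone signals, also had more Cngb1 in rd10 in the version-blocked fit, from 2.75 ± 0.610 CPM (SD, n = 3) to 79.1 ± 3.37 CPM (SD, n = 2). Galntl6, a glycosyltransferase gene, lay at 6.43 ± 6.49 CPM in rd1 and 1100 ± 1520 CPM in rd10, with log2 folds of 3.27 in the 6.0.1 and 7.25 in the 7.0.1 libraries. The chemokine gene Cxcl14 (-2.38), the calcium sensor gene Rcvrn (-1.88) and Igfbp5 (-1.51), a binding protein of insulin-like growth factors, fell.

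The planned edgeR fit called 0 of 14499 genes in cone bipolar cells, with 670 at an unadjusted p under 0.05 and 214 by DESeq2. The version-blocked fit called 1603, 850 higher and 753 lower, and 1001 without rd1 library 1. Cngb1 rose by a log2 fold of 4.78 (SE 0.161, version-blocked edgeR, Benjamini-Hochberg adjusted p = 3.34e-10) and had a Benjamini-Hochberg adjusted p of 0.0520 in the planned edgeR fit. Galntl6 (6.62), Rpl29 (2.68), Shisa4 (2.49), Cadm4 (1.93), Pde6h (1.87), AC149090.1 (1.73) and Slc24a5 (1.71) were the other largest rises, and AA465934 (-3.67), Rnf121 (-2.37), BC004004 (-2.0), Hddc3 (-1.65) and Syn2 (-1.61) fell besides those above. Rod phototransduction genes rose for 8 of 11, cone phototransduction genes rose for 9 of 19 and fell for 2, outer segment genes rose for 6 of 20 and photoreceptor synapse genes for 3 of 16. Their camera Benjamini-Hochberg adjusted p was 5.14e-22, 0.00236, 0.00414 and 0.0289, with adjusted p = 0.492, 0.492, 0.581 and 0.581 with an estimated correlation. Mitochondrially encoded genes rose for 8 of 13, with a camera Benjamini-Hochberg adjusted p of 7.02e-12 and an adjusted p = 0.492 with an estimated correlation.

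In amacrine cells, the inhibitory interneurons, 4 of 11 antigen presentation genes rose and 4 of 24 glycolysis genes fell in rd10 in the version-blocked fit. The camera Benjamini-Hochberg adjusted p was 5.34e-06 and 0.00236 for these lists, with adjusted p = 0.492 and 0.693 with an estimated correlation. The antigen presentation genes that rose were the class I genes H2-K1 (1.56), H2-D1 (1.33) and B2m (0.94) and the class II gene H2-Ab1 (4.48, at 0.0441 and 2.01 CPM), and 7 passed when adjusted over the list alone. The glycolysis genes that fell were Aldoc (-0.75), the lactate transporter gene Slc16a3 (-0.58), Eno2 (-0.54) and Pgam1 (-0.50), and 11 passed when adjusted over the list alone.

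The planned edgeR fit called 1 gene of 15596, Xist, with 736 at an unadjusted p under 0.05 and 185 by DESeq2, and the version-blocked fit called 1549, 815 higher and 734 lower. The planned fit called 0 genes without rd1 library 1, rd1 library 2, rd10 library 1 or rd10 library 2 and 8 without rd1 library 3, and the version-blocked fit called 1036 without rd1 library 2. Rpl29 (2.59), Pde6h (2.56), mt-Nd3 (2.04), Gngt1 (1.92), AC149090.1 (1.82), Slc24a5 (1.70), Mrpl27 (1.48) and Pdxdc1 (1.43) were the largest rises. AA465934 (-4.61), the cell cycle inhibitor gene Cdkn1c (-2.56, from 66.4 to 10.4 CPM), Rnf121 (-2.17), the serine synthesis gene Psat1 (-2.09), Hddc3 (-1.82), Wdfy1 (-1.66), Gsta4 (-1.65) and BC004004 (-1.61) were the largest falls. Of 14 interferon response genes 2 rose, among them Ifi27 (1.07), and of 21 nuclear oxidative phosphorylation genes 2 fell, Atp5g1 (-0.83) and Sdhb (-0.38). Their camera Benjamini-Hochberg adjusted p was 0.0458 and 0.0400, with adjusted p = 0.693 and 0.835 with an estimated correlation. Rod phototransduction genes rose for 9 of 11, cone phototransduction genes for 15 of 19, outer segment genes for 11 of 20 and mitochondrially encoded genes for 7 of 13. Their camera Benjamini-Hochberg adjusted p was 8.93e-36, 1.34e-22, 1.32e-11 and 5.46e-14, each with an adjusted p = 0.492 with an estimated correlation.

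Across cones, Müller glia, rod bipolar, cone bipolar and amacrine cells, 50 genes were higher and 29 lower in rd10 in all 5 classes in the version-blocked fit, of 9131 genes tested in all 5. The 5 classes come from the same 5 libraries, so their calls are not independent of each other. In at least 1 class 2061 genes were called, and 94 were called in opposite directions in different classes. Rpl29, a ribosomal protein gene, was among the largest rises in each of the 5 classes and AA465934 among the largest falls. Sex-linked genes differed in all 5 classes, so sex went with genotype at least in part. Xist, the RNA of the inactive X, lay at 2017 ± 189 CPM in rd1 and 1.72 ± 1.35 CPM in rd10 cones, and Y-linked Ddx3y at 19.8, 26.7 and 0 CPM in rd1 libraries 1, 2 and 3 and at 71.7 and 62.7 CPM in rd10 libraries 1 and 2. Of the 6 sex-linked genes listed, 4 were higher and 2 lower in rd10 in each of these classes. At the 3′ ends of transcripts, 57.7% of the sequence words of Rpl29, 73.5% of those of Trf, 20.6% of those of Hddc3 and 98.1% of those of mt-Nd3 occur in other genes too, so these values are uncertain.

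**Figure D5:**
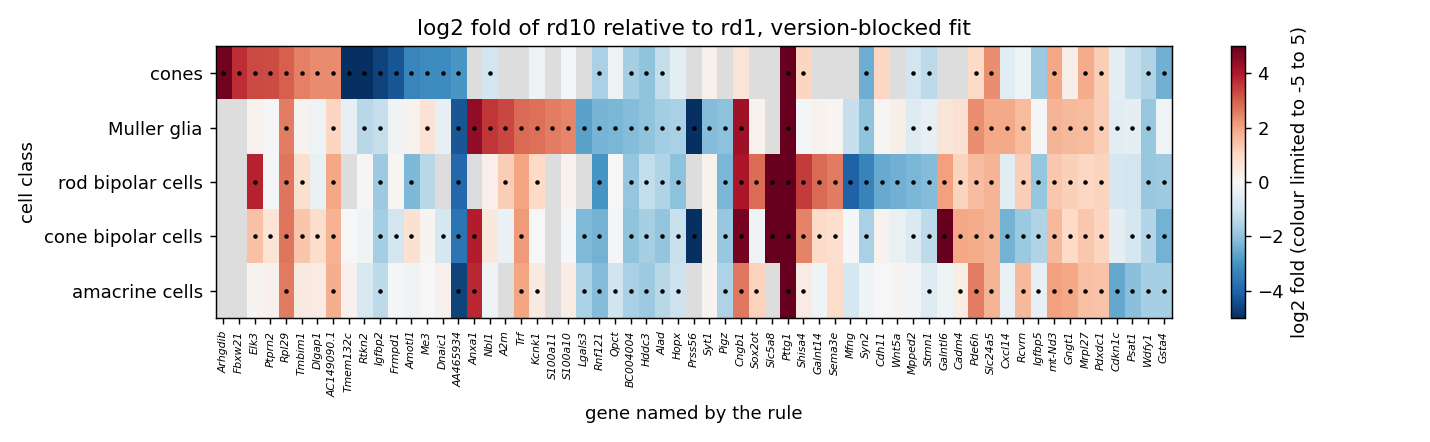
Log2 fold of rd10 relative to rd1 in the version-blocked fit (colour, limited to -5 to 5) for each named gene (x axis) in 5 cell classes (y axis), with dots for an adjusted p under 0.05 and grey where a gene was not tested. Rpl29 is higher in all 5 classes, at 2.97 in cones, and AA465934 is lower in all 5, at -4.61 in amacrine cells.

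By GRCm38 (mm10) coordinates, Opn1sw (ENSMUSG00000058831) lies on chromosome 6 from 29376671 to 29388468, Slc24a2 (ENSMUSG00000037996) on chromosome 4 from 86983124 to 87230477, and Pde6c (ENSMUSG00000024992) on chromosome 19 from 38132781 to 38183958. Pdc (ENSMUSG00000006007) lies on chromosome 1 from 150319417 to 150333906, Pde6b (ENSMUSG00000029491) on chromosome 5 from 108388391 to 108432397 and Kcnj6 (ENSMUSG00000043301) on chromosome 16 from 94748636 to 94997701. Cngb1 (ENSMUSG00000031789) lies on chromosome 8 from 95239045 to 95306585, Anxa1 (ENSMUSG00000024659) on chromosome 19 from 20373428 to 20390944, A2m (ENSMUSG00000030111) on chromosome 6 from 121635376 to 121679227, Igfbp2 (ENSMUSG00000039323) on chromosome 1 from 72824503 to 72852474 and Frmpd1 (ENSMUSG00000035615) on chromosome 4 from 45184875 to 45285936.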

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

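The tests of RNA from other cells below, and the version-blocked calls set beside the other tests, were chosen only after the data were seen.

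In cones, 179 genes differed between rd10 and rd1 in another way than in the remaining cells of the same libraries, 77 with a higher and 102 with a lower difference, by an edgeR interaction test over 15198 genes with the library as a block and Benjamini-Hochberg adjustment. Frmpd1 led them, with a difference of log2 folds of -4.54 (edgeR, Benjamini-Hochberg adjusted p = 1.17e-05). The same test gave 89 genes in Müller glia, 40 in rod bipolar cells, 33 in cone bipolar cells and 19 in amacrine cells. Of the genes called in the version-blocked fit of each class, 135, 77, 38, 24 and 11 differed from the other cells in this test.

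Within the cone phototransduction list, the cone against non-photoreceptor difference itself changed with genotype for 3 genes with adjustment over all genes, and for 8 with adjustment over the list alone. The change was -2.92 log2 units for Pdc, -2.50 for Guca1b and 1.28 for Slc24a2, and for the 5 others -1.51 for Grk1, -1.36 for Guca1a, -1.29 for Opn1sw, -1.03 for Pde6h and -0.40 for Gnb3. Of the 7 genes with a lower difference 6, all but Gnb3, also rose in rd10 in the version-blocked fit of 2 to 4 of the classes Müller glia, rod bipolar, cone bipolar and amacrine cells, in Müller glia by 2.00 for Pdc, 2.80 for Guca1b, 1.73 for Grk1, 1.38 for Guca1a, 1.10 for Opn1sw and 2.31 for Pde6h. Pde6h rose in cones as well (0.98), so its lower difference came with the rise in the other cells. In cones Pdc was lower in the version-blocked fit, while Guca1b lay at 49.7 CPM in rd1 and 49.3 CPM in rd10 and did not pass.

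Rods formed a class of 142 cells in rd10 library 2 and in no other library. Of these cells 77.5% had a Pde6b UMI and 66.2% a Cngb1 UMI, against 2.63% and 2.55% of Müller glia and 1.25% and 2.92% of cones in that library. Cells of the retinal pigment epithelium, a layer outside the neural retina, were found in rd1 library 3 (149 cells, 1.06%, 95% Wilson interval 0.904 to 1.24) and in rd10 library 2 (126 cells, 1.30%, 1.09 to 1.54). Their cluster scored 1.027 on the markers of this layer and 0.884 on Müller glia markers. The 3 libraries of Cell Ranger 6.0.1 held 0 such cells, but the cells found had medians of 820 and 784 genes in the deep libraries, and at the lower depth of 6.0.1 such cells can fall under the limit of 500 genes, so no limit on their share follows.

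Photoreceptor transcripts were higher in rd10 in Müller glia, rod bipolar, cone bipolar and amacrine cells. RNA from other cells, such as free RNA of rods and cones in the droplets, would give each class a like number of UMIs per cell. Of 38 photoreceptor genes that rose in at least 1 of these classes, 3 lay within a factor of 2 across the 4 classes in both rd10 libraries, which argues against one even pool as the source of them all. Cngb1 stood out: in the rd10 libraries its UMIs per rod bipolar or cone bipolar cell were at least 6.46 times those per Müller cell, which argues against RNA from other cells for this gene in bipolar cells. For the rise, free RNA of rods and cones (for genes other than Cngb1 in bipolar cells) stays open. Cones made up 4.80% of rd10 and 1.28% of rd1 cells, and rods were a class in rd10 library 2 alone. The amount of such RNA may thus differ between genotypes. Cells that carry RNA of a photoreceptor in part, doublets, age and genotype stay open as well. Expression of Cngb1 by bipolar cells may be a candidate explanation of their excess in both genotypes and was not tested further.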

How the results depend on the processing

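The fits with the Cell Ranger version as a block, the 6.0.1 libraries alone and each version or genotype alone were chosen only after the data were seen. So were cones without a rod transcript, the estimated correlation and all tests of the 4 further classes. The other alternatives were planned. For 26 genes in cones against other cells, 354 comparisons with an alternative or a library left out had the same direction and side of the threshold, 2 were weaker, 4 stronger and 1 reversed. The reversed one was Kcnj3, at a log2 fold of 0.43 against cone bipolar cells alone. Of 64 results for named genes of the planned fits, 708 comparisons had the same direction and side of the threshold, 232 were weaker, 24 stronger and 47 reversed. Of 272 results for named genes of the version-blocked fits the numbers were 2025, 318, 0 and 8. The stricter cell filter was not run for the genes of cones, since rd1 library 2 held 19 cones under it, and no alternative was run for microglia. The version-blocked fit was run without rd1 library 1 and without rd1 library 2; leaving out any other library leaves 1 version with a single genotype. Depth limited the shares of cones with a UMI: of 62 shares, 40 moved between thinned and all UMIs and 22 did not. The 6.0.1 libraries alone, and the fits without either rd10 library, hold 1 rd10 library, which is assumed to vary like the rd1 libraries that give all of the spread there. For all values below that moved, the cause was not tested, except that fits on fewer libraries or fewer genes change the number of tests and the spread by construction.

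In cones the planned fit called 1 gene, and the alternatives called 56 with DESeq2, 2 with DESeq2 size factors in edgeR, 114 with no filter on low counts (2 of the cone phototransduction list), 2 with a stricter filter, 2 with doublets kept, 317 in the 6.0.1 libraries alone (6 of the list), 543 with the version block (6 of the list) and 0 to 12 with each library left out. Version-blocked DESeq2 called 155 genes in cones and version-blocked thinned counts called 156. In Müller glia the planned fit called 63, DESeq2 529, no filter 97, a stricter filter 112, the stricter cell filter 39, the 6.0.1 libraries alone 3024 and the version block 1961, and leaving out each library gave 0 to 28. In rod bipolar cells the planned fit called 5, DESeq2 184, no filter 46, a stricter filter 36, thinned counts 2, the 6.0.1 libraries alone 719 and the version block 814, and leaving out each library gave 0 to 2. Version-blocked DESeq2 called 479 there, version-blocked thinned counts 496, and the version block with each rd1 library of 6.0.1 left out 504 to 833. In cone bipolar cells the planned fit called 0, DESeq2 214, DESeq2 size factors 3, no filter 10, a stricter filter 15, doublets kept 5, the stricter cell filter 2, thinned counts 1, the 6.0.1 libraries alone 2231 and the version block 1603. Version-blocked DESeq2 called 954 there, version-blocked thinned counts 993, and the version block with each rd1 library of 6.0.1 left out 1001 to 1526. In amacrine cells the planned fit called 1, DESeq2 185, no filter 9, a stricter filter 13, doublets kept 2, thinned counts 0 (edgeR), the 6.0.1 libraries alone 1127 and the version block 1549, and leaving out each library gave 0 to 8. Version-blocked DESeq2 called 823 there and version-blocked thinned counts 891. In the 4 further classes the planned fit called 26 genes in horizontal cells, 7 in astrocytes, 7 in ganglion cells and 1 in vascular cells, against 219, 35, 175 and 19 with DESeq2, 149, 242, 24 and 101 with no filter, 38, 26, 15 and 5 with a stricter filter, 18, 7, 0 and 1 with doublets kept, 10, 5, 4 and 1 with thinned counts, and 628, 58, 1209 and 123 in the 6.0.1 libraries alone (all edgeR but DESeq2). The version block called 669, 152, 1379 and 72 there, against 233, 41, 444 and 29 with version-blocked DESeq2, 950, 274, 1334 and 31 with doublets kept and 384, 98, 1161 and 18 with thinned counts. Of the gene list tests 25 passed camera in the planned fit and 30 with the version block, and 0 passed with an estimated correlation.

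With the sample number as a replicate block, edgeR called 1 gene in cones, 11 in Müller glia, 0 in rod bipolar cells, 31 in cone bipolar cells, 25 in amacrine cells, 1 in horizontal cells, 129 in astrocytes, 0 in ganglion cells and 6 in vascular cells, and 0 of the cone phototransduction list. The numbers do not pair the libraries: the 2 pairs had correlations across genes of 0.504 to 0.844 for number 1 and of -0.500 to -0.818 for number 2, which followed the Cell Ranger version.

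The share of cones was higher in rd10 by 3.52 percentage points, by 3.85 with doublets kept and by 3.82 among neurons and Müller glia, with log2 folds of 1.91 by edgeR on cell counts and 1.88 with the version block. With the stricter cell filter the difference of rd10 from rd1 was -0.274 percentage points for astrocytes, 8.63 for cone bipolar cells, -3.63 for ganglion cells, -0.788 for horizontal cells and 7.04 for rod bipolar cells. In the 6.0.1 libraries alone it was 1.99 for cone bipolar cells. In the 7.0.1 libraries alone it was 0.0484 for astrocytes, -2.15 for cone bipolar cells, 0.391 for microglia and 0.332 for vascular cells.

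The cone genes that reversed direction were past the threshold in no fit that reversed them, and ranges are those with each library left out. Gngt2 in cones ranged from -0.047 to 0.23 and was at -0.058 with the replicate block and -0.026 in the 6.0.1 libraries alone. Cngb3 in cones ranged from -1.40 to 2.69 and Thrb in cones from -0.50 to 1.90, lowest without rd10 library 2. Arr3 in cones ranged from -1.14 to 1.43 and was at -0.030 with a stricter filter and -0.080 with the version block. Grk1 in cones ranged from -0.37 to 0.40 and was at -0.0076 with a stricter filter, -0.12 with the replicate block, -0.012 with doublets kept and -0.026 with thinned counts. Guca1b in cones ranged from -0.32 to 0.26 and was at 0.24 with the replicate block, 0.069 with doublets kept and 0.25 in the 6.0.1 libraries alone. Gucy2e in cones ranged from -0.35 to 0.22 and was at 0.017 with no filter, 0.044 in the 6.0.1 libraries alone and 0.049 with the version block. Rgs9 in cones ranged from -0.41 to 0.32 and was at -0.030 with a stricter filter, -0.037 with thinned counts, -0.30 in the 6.0.1 libraries alone and -0.071 with the version block. Rgs9bp in cones ranged from -0.82 to 0.50 and was at 0.036 with no filter, 0.030 with doublets kept, 0.011 with the finer clustering, 0.18 with thinned counts, 0.032 in cones without a rod transcript, 0.11 in the 6.0.1 libraries alone and 0.10 with the version block. Gnb5 in cones ranged from -0.18 to 0.13 and was at -0.053 with a stricter filter, -0.23 with thinned counts, -0.16 in the 6.0.1 libraries alone and -0.014 with the version block.

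Among version-blocked values, with rd1 library 1 or 2 left out, Gucy2e in cones ranged from -0.023 to 0.058, Rgs9bp in cones from -0.077 to 0.27, Gnb5 in cones from -0.061 to 0.019 and Pde6b in cones from -0.38 to -0.12. Gucy2e in cones was at -0.16 with thinned counts, and with doublets kept Gnb5 in cones was at 0.015 and Pde6b in cones at -0.39.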

Other observations

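The test of shared sequence, the test of neighbouring genes and the test of introns below were set before their results were seen, while the tests of depth and the tests of the 4 further classes were chosen only after the data were seen.

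Horizontal cells, which feed back onto photoreceptors, held 26 genes past the threshold in the planned edgeR fit and 669 in the version-blocked fit. Without rd1 library 1 or rd1 library 2 the planned edgeR fit called 0 genes, without rd1 library 3 it called 11, and without rd10 library 1 or 2 it called 1 in each case. Olfml3, a secreted matrix protein gene, rose by a log2 fold of 3.85, from 18.6 to 264 ± 33.9 CPM (planned edgeR, Benjamini-Hochberg adjusted p = 0.0242). Thrsp rose by 3.49, from 20.9 to 234 CPM (planned edgeR, Benjamini-Hochberg adjusted p = 0.0109), and Megf10, an engulfment receptor gene, by 2.71. Alox5, the lipoxygenase of leukotriene synthesis, fell with a log2 fold of -3.08, from 116 to 13.6 CPM, the homeobox gene Shox2 with -2.73, from 124 to 18.6 CPM, Wdfy1 with -3.12, from 151 to 17.2 CPM, and Cplx3, a complexin of ribbon synapses, with -1.98, from 385 to 97.2 CPM. All 13 mitochondrially encoded genes rose in the version-blocked fit, with a camera Benjamini-Hochberg adjusted p of 9.41e-43 and an adjusted p = 0.536 with an estimated correlation. Of 11 immediate early genes 5 fell, with a camera Benjamini-Hochberg adjusted p of 1.28e-05 and an adjusted p = 0.536 with an estimated correlation.

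Astrocytes, the glia of the nerve fibre layer, held 7 genes past the threshold in the planned edgeR fit and 152 in the version-blocked fit. The planned fit called 2 genes without rd1 library 1 or rd1 library 2, 21 without rd1 library 3 and 3 without rd10 library 2, and the version-blocked fit called 80 without rd1 library 1. Libraries held as few as 26 astrocytes, in clusters with median doublet scores of 0.208 and 0.194. Mgp, the matrix Gla protein, lay at 2338 ± 269 CPM (SD, n = 3) in rd1 and had 0 UMIs in both rd10 libraries. It was at least 528-fold lower in rd10, from 2095 unscaled CPM in rd1 against a floor of 3.97 CPM over the rd10 libraries. Rgs5, a marker of pericytes, rose from 87.0 to 1137 CPM (log2 fold 3.75, planned edgeR, Benjamini-Hochberg adjusted p = 0.0470), and C4b, a complement gene, rose by 2.51 in the version-blocked fit, from 139 to 716 CPM. Ganglion cells held 7 and 1379 genes, among them Ahnak2, higher by 2.71 in the version-blocked fit, from 36.1 to 217 CPM, and with any 1 of the 5 libraries left out the planned edgeR fit called 0 genes there. Of 15 immediate early genes 6 rose in ganglion cells, with a camera Benjamini-Hochberg adjusted p of 0.00208 and an adjusted p = 0.612 with an estimated correlation, and 3 of 19 cholesterol synthesis genes fell, with a camera Benjamini-Hochberg adjusted p of 0.000165 and an adjusted p = 0.612 with an estimated correlation. Vascular cells held 1 and 72 genes, with 2 in the planned fit without rd1 library 3 or rd10 library 1 and 125 in the version-blocked fit without rd1 library 1, among them the adhesion molecule gene Vcam1, higher by 3.31 in the version-blocked fit, and 3 of 22 interferon response genes rose there, with a camera Benjamini-Hochberg adjusted p of 0.000498 and an adjusted p = 0.536 with an estimated correlation.

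By markers alone, microglia numbered 79, 80 and 38 cells in rd1 libraries 1, 2 and 3 and 65 and 45 cells in rd10 libraries 1 and 2 before doublets were removed. The removal took 25, 15, 36, 23 and 3 of them in that order, so the count in rd1 library 3 rested on the doublet step.

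The 79 genes that changed the same way in all 5 classes were weighed against technical sources. At their 3′ ends 22 of 79 (27.8%, 95% Wilson interval 19.2 to 38.6) shared 31-base words with another gene, against 630 of 9052 other genes (6.96%; Fisher's exact test, two-sided, odds ratio 5.16, p = 2e-08), which argues against shared reads as the source of all 79 and leaves them open for those 22. Of the 67 autosomal genes, 15 had another gene of the set within 1 Mb, against a median of 7 and a highest value of 19 in 2000 random sets, of which 44 had as many, which is consistent with strain variants in shared blocks of the genome. None of the 67 autosomal genes lay within 10 Mb of Pde6b, against 115 other genes (1.31%). That share is too low for a set of 67 genes to show a difference, so this count decides nothing. Sex, with 4 genes on the X and 5 on the Y chromosome, age and the Pde6b alleles may each contribute to the rest, and strain background cannot be told apart from genotype in this design.

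The libraries also separated by Cell Ranger version. A split of the 5 libraries by version called 1596 genes in cones, 4635 in Müller glia, 3114 in rod bipolar cells, 6356 in cone bipolar cells and 6418 in amacrine cells, more than the split by genotype (1, 63, 5, 0 and 1), while each of the 8 other splits called 0 by edgeR. Genes with the longest introns lay higher against genes with no intron in the 7.0.1 libraries, by between 0.836 and 1.51 log2 units over 5 classes and both genotypes, which is consistent with intron reads counted in 1 version alone. With counts thinned to the lowest total of the class, at least 70.9% of the calls between versions were still made in Müller glia, rod bipolar, cone bipolar and amacrine cells, which argues against depth as their whole source. In cones 38.3% were still made, which leaves depth open there, and a difference between preparation days may add to the split and was not tested.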
